A study of Homo sapiens with 36 samples.

How the data were processed

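Libraries were made by transposition of nuclei and paired-end sequencing, per the labels' protocols, from T47D, ZR751 and MCF7 cells treated in triplicate with DMSO or 30 nM inhibitor for 48 or 120 hours. The groups (line, treatment and time) were taken from the labels. Nothing in the labels says whether the triplicates came from separate cultures.

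The authors deposited 12 lists of regions, each with a chromosome, start, end, name and a score, a whole number that falls from the top to the bottom of a list. What the score is was not stated in the sources used here; its highest value in any list is 5000, which 8 regions share, its lowest 8, and it was used to rank regions within a list and, with one bound for all lists, to filter them. Per the names of the deposited lists, regions passed a 2-fold change and an FDR of 0.05 for inhibitor against DMSO; the fold, FDR and test of each region, the counts per library and the set of all tested regions were not used here. Per the submitters' processing notes, Bowtie2, SAMtools, MACS2, bedtools, deepTools and the hg38 build were used; their versions and roles, and whether regions were called per library or on pooled reads, are not given in the sources used here. Regions on both days of a set had identical coordinates in 1508 of 1508 cases, and no region had the same coordinates in 2 sets. Because a list holds regions past a threshold, its length depends on the depth and replicate spread of its libraries as well as on the response, so the number of regions was not tested between lines. Any shift of reads for the transposase and any scaling between libraries are likewise not given, and a scaling that moved all regions of a comparison in one direction would move its share lost.

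Of the lists, 8 name ZR751 or MCF7 and 4 name no line. Although the labels hold a further line, T47D, the unnamed lists were kept as a set of their own and not assigned to it. Positions are 1-based on hg38. No genome sequence was used, and the only annotation was a table of gene positions on GRCh38.p14 without strand, exons or transcripts. As a check of the build, 4.39% of all entries lay within 1 kb of a protein-coding gene end, against 2.65% and 2.70% after shifting them by 100 kb either way. For the same reason the planned transcription start site was replaced by either end of a protein-coding gene, the promoter share by the share within 1 kb of a gene end, and exon, intron and UTR shares by a split into gene end, inside a gene and between genes. The split counted protein-coding genes only, so a region called between genes may lie inside another annotated gene. The planned motif and GC comparisons needed sequence and were not run.

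Each region was assigned to the protein-coding gene with the nearest end, measured from the region centre. A gene counted as lost or gained by which direction had more of its regions, ties left out. The 14 gene lists (estrogen receptor targets, luminal identity, basal and myoepithelial, mesenchymal, immune, endothelial and adipocyte, cell cycle and E2F targets, MYC and growth, arrest and senescence, AP-1 and immediate early, interferon, HOX, histone acetyltransferases and KAT6 complex, neuronal) were fixed before the data were examined, with 342 distinct genes, all found in the annotation. List members were tested against all other assigned genes of the comparison by direction with a two-sided Fisher exact test. Comparisons with fewer than 20 genes in a direction (MCF7 on day 2) were not tested. With no set of all tested regions, the opposite direction of the same comparison served as the background throughout. Shares were tested with two-sided Fisher exact tests, the equality of 2 odds ratios with an exact test on fixed margins, and widths and the direction of neighbours with 10000 permutations. Permutations of neighbours within chromosomes numbered 2000, and those within windows of 5 Mb 1000. The p-values were adjusted by Benjamini-Hochberg within each family, except those of the neighbour tests and of the tests of explanations, which were not adjusted. Overlap meant at least 1 bp; the counts matched those of bedtools. The list test was tested on simulated data for ZR751 on day 5, where it called 5.0% of lists with an odds ratio of 1.

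Named genes followed a rule fixed before the data were examined: KAT6A, KAT6B and ESR1 in every comparison; the 5 genes with most lost and most gained regions per comparison; up to 4 members per list and comparison with most regions; up to 10 genes per direction with gene-end regions in the most comparisons; each gene of a list with 12 or fewer regions; and the first 5 genes by score per list. LOC, RP and readthrough names were left out. Further list members named beyond these were chosen after their values were seen.

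Alternatives were merging of regions under 1 kb apart, autosomes, a score of at least 50, other overlap rules, other windows around gene ends, all annotated genes, other gene assignments, regions as the unit and other distances for neighbours. Software was Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.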

Results

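ATAC-seq, which reads accessible chromatin by the insertion of a transposase, was performed on 36 libraries from 3 breast cancer cell lines that express the estrogen receptor: T47D, ZR751 (ZR-75-1) and MCF7. Each line received vehicle (DMSO) or 30 nM of PF-9363, also called CTx-648, an inhibitor of the histone acetyltransferases KAT6A and KAT6B. Cells were collected after 2 or 5 days, which gave 12 groups of 3 libraries. The data analysed here were 12 lists with 9449 region entries in all, 1 for regions with lower and 1 for regions with higher accessibility under inhibitor, for each of 3 sets of libraries and both days. Lower regions are called lost and higher regions gained. Of the sets, 1 is named ZR751, 1 is named MCF7 and the names of the remaining 4 lists give no cell line, so those lists were not assigned to a line. The lists hold positions and a score, with no value per library, so the depth of each library is unknown and the spread between replicates enters only through the threshold that the list names state (2-fold, FDR 0.05). Tests below treat regions or genes as independent units and say nothing about variation between cultures. Neighbouring regions are not independent, and neither are the lists of 2 days of a set, which share many regions.

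The first question was how many regions were listed for each set and in which direction. ZR751 had the longest lists: 886 regions were lost and 667 gained on day 2, and 3563 were lost and 2717 gained on day 5. Lost regions made up 57.1% of the ZR751 entries on day 2 (95% Wilson interval 54.6 to 59.5) and 56.7% on day 5 (55.5 to 58.0). MCF7 had 15 lost and 5 gained regions on day 2, and 83 lost against 409 gained on day 5, a share lost of 16.9% (13.8 to 20.4). In the set that names no cell line, 238 regions were lost and 36 gained on day 2 (86.9% lost, 82.3 to 90.4), and 497 were lost and 333 gained on day 5 (59.9% lost, 56.5 to 63.2). The intervals cover counting error only.

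**Figure D1:**
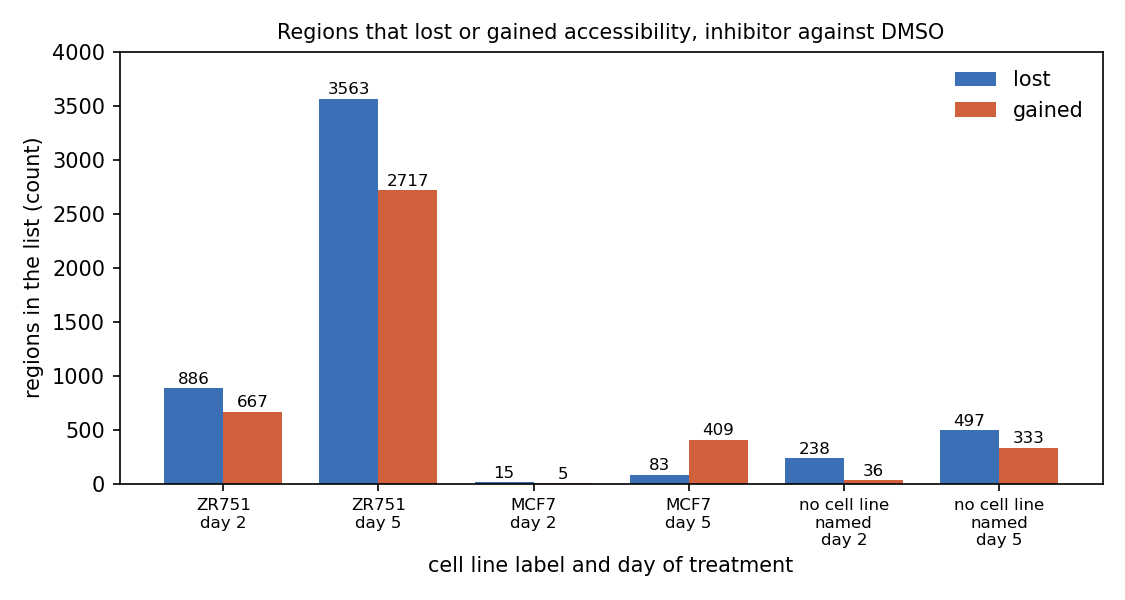
Number of regions that lost (blue) or gained (orange) accessibility under inhibitor against DMSO, by cell line label and day of treatment; the vertical axis counts list entries, and there are no error bars because each list is 1 count. The ZR751 lists of day 5 hold 3563 lost and 2717 gained regions, while MCF7 on day 5 holds 83 lost and 409 gained.

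The share lost differed between sets on day 5: it was higher in ZR751 than in MCF7 (odds ratio 6.46, two-sided Fisher exact test, adjusted p = 3.505e-68) and higher in the unnamed set than in MCF7 (adjusted p = 6.231e-55). Between ZR751 and the unnamed set the difference on day 5 did not pass the threshold (adjusted exact p = 0.129), whereas on day 2 the unnamed set had the higher share (adjusted p = 9.09e-23). From day 2 to day 5 the share lost fell in MCF7 (75% to 16.9%, adjusted exact p = 8.02e-08) and in the unnamed set (86.9% to 59.9%, adjusted p = 1.33e-17). These tests took the days as independent and ignored the regions listed on both. Such regions were 14 of the 20 of day 2 in MCF7 and 240 of 274 in the unnamed set. Lost entries did not decrease in either set (15 to 83 and 238 to 497): gained entries increased more (5 to 409 and 36 to 333), in lists whose length also depends on depth and replicate spread. In ZR751 the change did not pass the threshold (odds ratio 1.01). Benjamini-Hochberg adjustment was over 9 tests. Among regions with a score of at least 50, a bound chosen after the scores were seen and taken as the same in every list although the meaning of the score is not stated, the ZR751 difference between days did pass (odds ratio 1.28, adjusted exact p = 0.00667).

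In ZR751 on day 5, estrogen receptor target genes lay near lost regions. Of 40 genes on this list, 27 had more lost than gained regions, 1 (AGR3, with 0 lost and 2 gained) had more gained, NRIP1 had 1 of each and 11 had none. GREB1, an estrogen-induced growth regulator, had 11 lost regions. BCL2, an inhibitor of apoptosis, had 6, and CCND1 (cyclin D1), CTSD (the lysosomal protease cathepsin D), HSPB8 (a small heat shock protein) and SLC7A5 (an amino acid transporter) had 4 each. PGR, the progesterone receptor, RARA, a retinoic acid receptor, CXCL12, a chemokine, IGF1R, a growth factor receptor, and SIAH2, a ubiquitin ligase, had 3 each, and none of these genes had a gained region. Against all other genes with a listed region, the odds ratio for lost over gained was 20.8 (two-sided Fisher exact test, p = 3.17e-06, adjusted p = 0.000222 over 70 tests of 14 lists in 5 comparisons). The adjusted p ranged from 5.855e-12 to 0.0204 over the other settings. Counts per gene depended on the assignment: within 10 kb of a gene end, lost minus gained regions came to 0 for GREB1, 1 for BCL2 and 3 each for HSPB8 and SLC7A5, and with all annotated genes to 2 for GREB1, 3 for BCL2 and SLC7A5 and 0 for HSPB8. No p-value per gene exists in these data, so no count adjusted over the list alone can be given.

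On day 2 the same list stood at 15 genes lost and 1 gained in ZR751, with GREB1 at 11 lost regions, IGF1R at 4 and CCND1, CTSD, CXCL12 and SLC7A5 at 2 each. Its adjusted exact p was 0.0522 (odds ratio 12.4, p = 0.00149). The call depended on the setting. With regions instead of genes as the unit the adjusted p was 9.397e-06, and with lists that had no member near a region left out of the adjustment it was 0.0366. It was 0.0947 with assignment by gene span, 0.639 within 10 kb of a gene end and 1 with all annotated genes. The smaller adjustment and the gene span were added after the data were seen. Within 10 kb, lost minus gained regions on day 2 came to 0 for GREB1, IGF1R and CCND1, and with all annotated genes to 2 for GREB1 and 0 for IGF1R, CCND1 and CTSD. In the set that names no cell line, 6 of these genes were lost and 1 gained on day 2, much as among other genes (odds ratio 1.05, adjusted exact p = 1), and 11 were lost and 3 gained on day 5 (adjusted p = 0.875), with 3 lost regions each at FHL2, GREB1 and NRIP1. In MCF7 on day 5, AGR3 was lost (1 region), and EGR3 and NRIP1 were gained (1 region each). The odds ratios of this list did not differ past the threshold between ZR751 and MCF7 on day 5 (exact test of equal odds ratios, p = 0.243), between ZR751 and the unnamed set on day 2 (p = 0.175) or day 5 (p = 0.101), or between the days in ZR751 (p = 1).

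**Figure D2:**
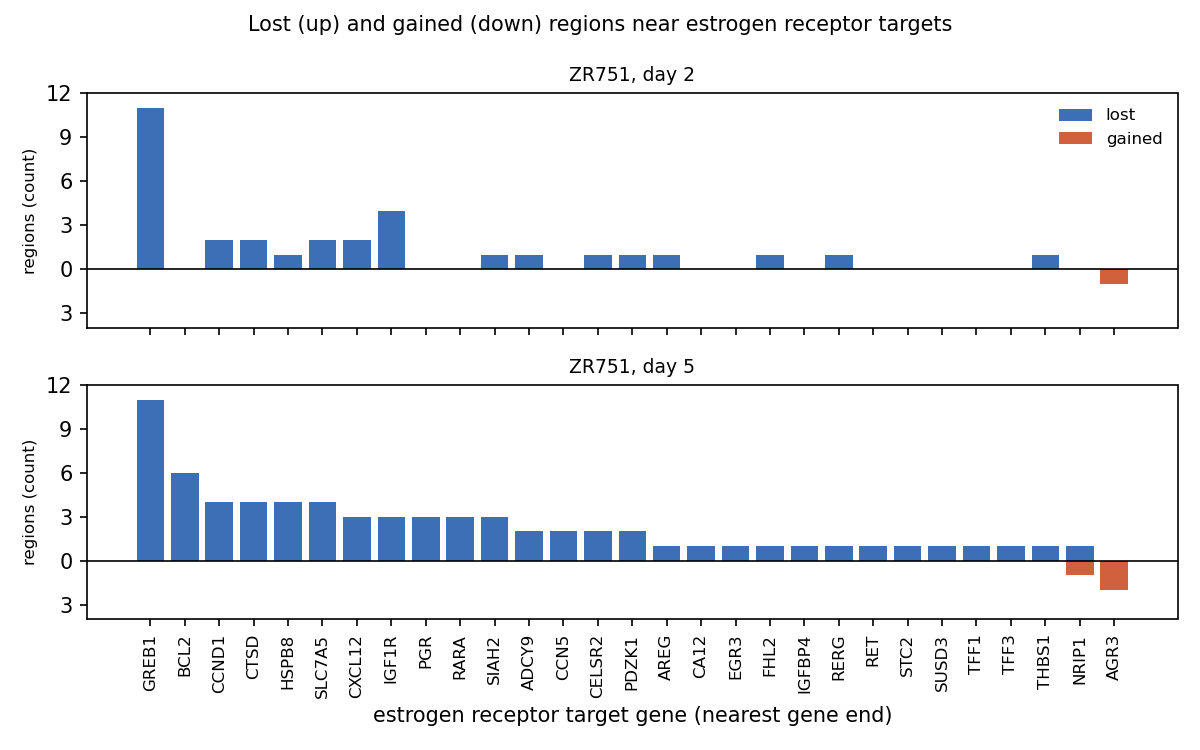
Number of lost (blue, upward) and gained (orange, downward) regions whose nearest gene end belongs to each estrogen receptor target with a listed region in ZR751, on day 2 (upper panel) and day 5 (lower panel); bars are counts and have no error bars. GREB1 has 11 lost regions on both days, and AGR3 is the gene with more gained than lost regions.

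The regions at GREB1 lay within the gene, which spans positions 11482888 to 11642788 of chromosome 2 (hg38); whether they are exonic or intronic was not resolved. The highest ranked of the ZR751 regions on day 5, at 11530418 to 11531489, was 29th of the lost list, and all 11 positions were listed on both days. In the unnamed set, 2 lost regions on day 2 and 3 on day 5 lay in the gene, the higher ranked of those on day 2 at 11530625 to 11531487, and MCF7 had none. At CCND1, the cell cycle regulator cyclin D1, the top ZR751 region lay outside the gene on chromosome 11 at 69514478 to 69516233, 126 kb from the nearest gene end; it ranked 3rd of the lost regions on day 2 and was 1 of 8 that shared the highest score, 5000, on day 5. A lost region at 69514816 to 69515996 in the unnamed set, present on both days, overlaps it.

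**Figure D3:**
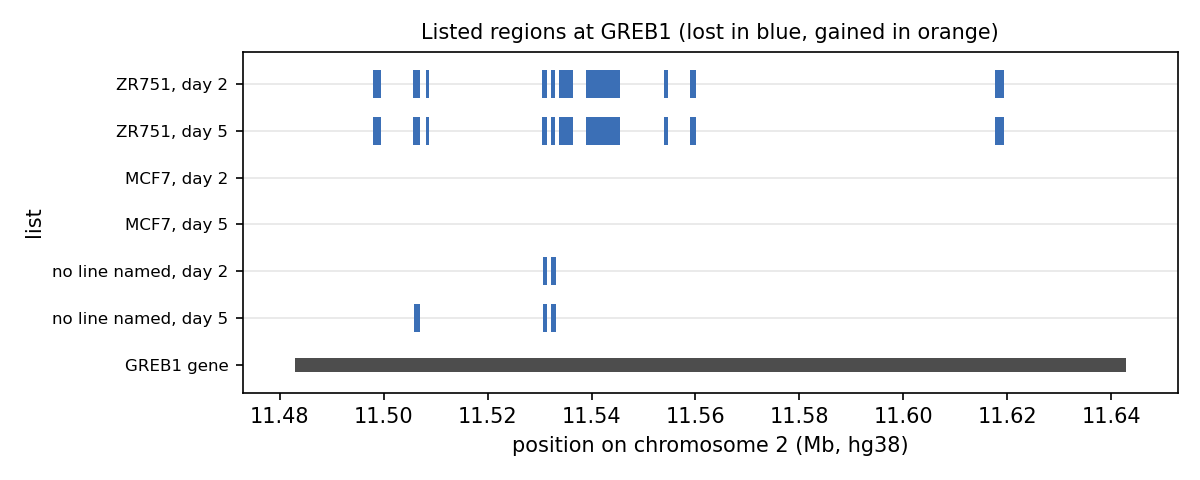
Map of the listed regions at GREB1, with the position on chromosome 2 (hg38, Mb) on the horizontal axis and a row for each list label and day; blue blocks are lost regions and the grey bar is the gene span. The 11 ZR751 regions recur on both days, the unnamed set has 2 on day 2 and 3 on day 5, and the MCF7 rows are empty.

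The genes with most lost regions in ZR751 on day 5 were PREX1, an exchange factor for Rac, and MYC, the growth-promoting transcription factor, with 12 each, followed by GREB1 with 11 and by SULF2, an extracellular sulfatase, and PLXNA2, a semaphorin receptor, with 9 each. MYC also had 2 gained regions. Of its lost regions, 1 covers a gene end at positions 127741966 to 127743893 of chromosome 8 and was also lost on day 2. The others lay between protein-coding genes, 108 kb or farther from MYC. Their assignment to MYC therefore rests on it being the nearest protein-coding gene, with non-coding genes not considered. Among the 2717 gained regions of day 5, the gene with the highest count was GATA6, an endodermal transcription factor (7 regions). DUSP10 (a MAP kinase phosphatase), ERC2 (a presynaptic scaffold protein), LYZL1 (a lysozyme-like protein) and RHOBTB1 (a Rho-related protein) had 6 each. DUSP10, ERC2 and RHOBTB1 also had 1 lost region each. Within 10 kb of a gene end, lost minus gained regions came to 0 for PREX1 and PLXNA2, 1 for MYC, 2 for SULF2 0 for ERC2, LYZL1 and RHOBTB1, and -1 for GATA6 and DUSP10, and with all annotated genes RHOBTB1 had 1 more lost than gained region. On day 2, TRPC6, a cation channel, and RBBP8, a DNA repair factor, had 5 lost regions each, GPR139, an orphan receptor, and MPPED1 had 4, NXPH1 had 4 gained regions, ANKRD50, CTNNA3 and DPT had 3, and C4BPA, a complement regulator, had 2. Within 10 kb, lost minus gained regions on day 2 came to 1 for TRPC6, to -1 for C4BPA and to 0 for RBBP8, GPR139, MPPED1, NXPH1, ANKRD50, CTNNA3 and DPT, and with all annotated genes to 1 for GPR139, -1 for C4BPA and 0 for the others.

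By score, the authors' own value, used here to rank regions within a list, 8 regions stood first in the ZR751 lost list on day 5. They shared a score of 5000, so they have no order among themselves. They were assigned to TSKU, GRIK3, ERBB4, CIMIP1 (96.1 kb away), MYOG, CCND1 (126 kb away), PPP1R26 and IFITM10. The ERBB4 region, inside the gene for this receptor tyrosine kinase, is at 211434792 to 211436208 of chromosome 2. The gained list began with IRF6, a transcription factor of epithelial cells, with a region inside the gene at 209786908 to 209788424 of chromosome 1, and continued with NEDD9, CLEC20A, PACS1 and GATA3. The region counted for GATA3 lay 1163 kb from it, and that counted for CLEC20A 137 kb from it, inside RASAL2. On day 2 the lost list began with CIMIP1 (96.1 kb away), ADAMTS15 (128 kb), CCND1 (126 kb), MYOG (3.34 kb) and ZMAT4 (66.6 kb from a gene end, inside the gene). The gained list began with CYRIA (250 kb away), DPT (116 kb), INPP4B (297 kb from a gene end, inside the gene), ASB7 (63.0 kb) and CD55 (39.0 kb).

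The other lists did not pass the threshold in ZR751 on day 5. Of the luminal identity genes, a list of luminal and general epithelial genes, 10 were lost, 5 gained and 2 tied (adjusted exact p = 1): KRT18 had 3 lost regions, while TBX3 had 4 gained ones. ESR1, the gene for the estrogen receptor, had 3 lost regions and 1 gained region on day 5 and 1 lost region on day 2. Mesenchymal markers stood at 8 lost and 0 gained (adjusted exact p = 0.278), among them MMP2 with 2 regions. MYC and growth genes stood at 3 lost and 0 gained (adjusted exact p = 1), with ODC1 at 2 lost regions. Cell cycle arrest and senescence genes stood at 3 lost and 7 gained (adjusted exact p = 0.875): IGFBP3 had 5 gained regions and CDKN2B, an inhibitor of cyclin-dependent kinases, had 4. Interferon response genes stood at 0 lost and 4 gained, namely IFI6, IFIT2, OAS1 and STAT1 with 1 region each (adjusted exact p = 0.554), and HOX genes at 0 lost and 3 gained, namely HOXB1, HOXB3 and HOXC11 (adjusted p = 0.819).

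Neuronal genes stood at 10 lost and 4 gained in ZR751 on day 5, basal and myoepithelial markers at 3 and 3, AP-1 and immediate early genes at 3 and 2, and cell cycle and E2F targets at 2 and 2. Immune cell markers stood at 1 lost and 2 gained, and endothelial and adipocyte markers at 2 and 1. Of 20037 protein-coding genes 3909 had a region in this comparison, as did 3 of 16 immune, 3 of 11 endothelial and adipocyte, 8 of 26 mesenchymal, 15 of 23 neuronal and 29 of 40 estrogen receptor target genes; these shares were not tested. For the neuronal, basal and myoepithelial, AP-1, cell cycle, immune, and endothelial and adipocyte lists the adjusted exact p was 1. Of the histone acetyltransferases and KAT6 complex genes, KAT6B had 1 gained region in ZR751 on day 5, 38.5 kb from a gene end, and BRD1 had 1 lost region on day 2; KAT6A had no region in any list. On day 2 in ZR751, 4 arrest and senescence genes were gained and 0 lost (IGFBP3, IGFBP7, MDM2 and TP53INP1, adjusted exact p = 0.554), and luminal identity genes stood at 7 lost and 1 gained (adjusted p = 0.819). No detection rate was simulated for lists with so few members, so a list that did not pass the threshold was not shown to be unchanged.

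The MCF7 lists were short on day 2. The 5 gained regions were assigned to RAD51B, a DNA repair gene, PTPRU, NFX1, CFAP299 and ELP1: the PTPRU region lay between genes, 647.7 kb away, and the others inside the gene, at RAD51B and CFAP299 106 kb and 133 kb from its ends. The named lost regions were assigned to SYNDIG1, ARID2 (133 kb away), AGR3, FAM47C (147 kb), KCNU1 (126 kb), BFSP2, FIGN and MAPT. Among the 409 gained regions of day 5, the gene with the highest count was RAD51B (5 regions, all inside the gene). TBL1XR1, a subunit of nuclear corepressor complexes, and PLXNA4, a semaphorin receptor, had 4 each, and CDH17 and ZFHX3 had 3 each. Within 10 kb of a gene end no region remained for RAD51B, TBL1XR1 or ZFHX3 and 1 for PLXNA4 and CDH17. By score the gained list began with ZFP36L1 (1.91 kb away), ASB7 (63.2 kb), MCTP2 (402 kb), TSKU (12.5 kb) and OR5C1 (10.6 kb). The lost list began with CIMIP1 (95.9 kb away), ARID2 (133 kb), PLAAT2 (6.11 kb from a gene end, inside the gene) and SPANXN4 (77.2 kb). Lost regions were scattered, with 2 near CTTNBP2 and 1 each near AGR3, CFP, NCOA5 and SERPINF1. Luminal identity genes stood at 0 lost and 4 gained (GATA3 with 2 regions, KRT7, RUNX1 and TFAP2A with 1 each), in a comparison where most genes were gained (adjusted exact p = 1). ESR1 and KAT6B had no region in either MCF7 comparison.

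In the set that names no cell line, JAK1, a cytokine receptor kinase, and SATB1, a chromatin organizer, had 4 lost regions each on day 2, as did MED13L, a Mediator subunit, BOD1 and SLC25A48. On day 5, SATB1, NDST4 and SH2D4B had 5 lost regions, and TPRG1 and the transcription factor gene GATA4 had 4. The NDST4 regions lay at least 242 kb and the SH2D4B regions at least 250.2 kb from their gene, and of the SATB1 regions 1 lay within 10 kb. Gained regions on day 5 were most frequent near ADGRF1, an adhesion receptor, ELAC2, a tRNA processing enzyme, RAD51B and CFAP58, with 3 each; RAD51B also had 2 lost regions. Within 10 kb of a gene end, lost minus gained regions came to 0 for JAK1, BOD1 and SLC25A48 on day 2 and for NDST4, SH2D4B, GATA4, ELAC2 and RAD51B on day 5. The top regions by score were assigned to CDKN3 in the lost lists of both days, 145 kb away and between genes, to PRKAA1, a catalytic subunit of the energy sensor AMPK, in the gained list of day 2, and to EHHADH, a peroxisomal enzyme, in that of day 5. ESR1 had 1 lost region on both days, inside the gene at 151806564 to 151809806 of chromosome 6. Of the luminal identity genes, 6 were lost, among them TRPS1 with 3 regions and GRHL2 with 2, and 1 (TBX3) was gained on day 5 (adjusted exact p = 1).

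The next question was whether the early response persisted. Within each set, regions present on both days had the same coordinates (1508 of 1508), and none changed direction: 1254 of 1254 in ZR751, 14 of 14 in MCF7 and 240 of 240 in the unnamed set, where the margins alone give 54.3%, 59.2% and 80.0%. Genes, called by the direction of most of their regions, did change: of those lost on day 2 in ZR751, 581 of 690 were lost and 33 gained on day 5, and of those gained 356 of 557 were gained and 47 lost. In MCF7, 2 of 15 lost genes and 0 of 5 gained ones had the opposite call, and in the unnamed set 0 of 189 and 0 of 33. Of the regions lost on day 2 in ZR751, 810 (91.4%) were lost again on day 5, and of those gained 444 (66.6%) were gained again. In the unnamed set, 213 of 238 lost regions (89.5%) and 27 of 36 gained ones (75%) returned, and in MCF7 10 of 15 and 4 of 5. The DMSO libraries of the 2 days are separate, so these comparisons share no control. A region missing from a list did not pass a threshold, which does not show that it did not change.

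Few regions were shared between sets, and most of these had the same direction. On day 5, 41 ZR751 regions overlapped an MCF7 region by at least 1 bp, with 13 lost in both, 22 gained in both and 6 lost in ZR751 and gained in MCF7 (85.4% the same against 51.3% expected from the margins, 95% Wilson interval 71.6 to 93.1, two-sided Fisher exact test, adjusted p = 2.772e-06). ZR751 and the unnamed set shared 151, of which 141 had the same direction (93.4% against 61.0% expected, 88.2 to 96.4, adjusted exact p = 1.024e-23), and MCF7 and the unnamed set 14, all with the same direction (54.1% expected, adjusted p = 0.000749). On day 2, ZR751 and the unnamed set shared 48, all with the same direction (81.3% expected, adjusted exact p = 1.31e-06), and so had the 2 regions shared by ZR751 and MCF7 (50% expected) and the 3 shared by MCF7 and the unnamed set (100% expected, adjusted p = 1 for both). With no list of all tested regions, the overlap that chance would give is unknown. Under all 3 labels, 3 regions were listed. A region inside JAK1 (chromosome 1, 65043972 to 65045142 in MCF7) was lost in each. So was a region between genes (chromosome 20, 58054139 to 58055839), 95.9 kb from CIMIP1, which codes for a ciliary microtubule protein. A region nearest CFAP58 (chromosome 10, 104479848 to 104481959) was lost in ZR751 and gained in MCF7 and the unnamed set.

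Most regions lay away from gene ends. On day 5 in ZR751, 257 of 3563 lost regions (7.21%, 95% Wilson interval 6.41 to 8.11) and 79 of 2717 gained ones (2.91%, 2.34 to 3.61) had their centre within 1 kb of either end of a protein-coding gene, an odds ratio of 2.60 (two-sided Fisher exact test, adjusted p = 6.242e-14 over 6 tests). Among only as many top-scored regions as the day 2 lists hold, the odds ratio was 1.57 (exact test, p = 0.114), and among regions with a score of at least 50 it was 2.47 (adjusted p = 4.652e-08). It was smaller, and still past the threshold, with a window of 2500 bp (1.85, adjusted exact p = 3.08e-10) and with all annotated genes (1.66, adjusted p = 1.988e-08). On day 2 the shares were 2.37% and 2.55% (adjusted exact p = 1). In the unnamed set on day 5 they were 4.43% and 1.5% (p = 0.0263, adjusted exact p = 0.0790), an odds ratio of 3.04 that turned to 0.805 with a window of 2500 bp (adjusted p = 0.557), and in MCF7 on day 5 2.41% and 2.20% (adjusted p = 1). At gene ends, PDZK1, a scaffold protein and estrogen target, was lost in 3 comparisons (ZR751 on both days and the unnamed set on day 5), with the unnamed set's region at 145706766 to 145708838 of chromosome 1. ACE2, a surface peptidase, was gained in the same 3 comparisons. MYC, SCGB2A2 (mammaglobin), CTHRC1, KCNH2 (a potassium channel), HBZ, CA10 and PLCXD3 were lost on both days in ZR751, DLGAP3 on both days in the unnamed set, and MYEOV on day 5 in ZR751 and the unnamed set. OAS1, an interferon-induced enzyme, BTN3A3, UACA, ADGRF1, ARL14 and TMPRSS11F were gained on both days in ZR751, PIP in ZR751 and the unnamed set on day 5, and TNFSF15 and TCHHL1 in ZR751 and MCF7 on day 5. Inside protein-coding genes but away from their ends lay 42.4% of lost and 45.2% of gained regions in ZR751 on day 5, and between protein-coding genes 50.4% and 51.9%.

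Lost and gained regions were grouped along the chromosomes. Of 2042 neighbouring pairs under 100 kb apart in ZR751 on day 5, 81.9% had the same direction, against 50.9% on average when directions were permuted (one-sided permutation test, p = 1e-04, the smallest that 10000 permutations can give). The share was 82.4% against 51.0% in ZR751 on day 2, and 97.8% against 77.0% on day 2 and 94.3% against 51.9% on day 5 in the unnamed set, each with permutation p = 1e-04. In MCF7 on day 5 it was 94.7% of 38 pairs against 71.9% (permutation p = 0.0004), a call that ended when only pairs under 10 kb apart were used (85.7%, p = 0.364). Chromosomes 11, 16, 19 and 20 held larger shares of the lost than of the gained regions in ZR751 on day 5, as on chromosome 19 with 4.35% against 0.810% (adjusted exact p = 1.959e-17), and chromosomes 3, 6, 7, 10 and 15 held smaller ones, as on chromosome 6 with 2.47% against 7.58% (adjusted p = 3.85e-19). These 9 calls of ZR751 on day 5, and the 2 on day 2 (chromosomes 2 and 16), fell to 0 when regions of a list under 1 Mb apart were merged, which left 936 lost and 876 gained regions on day 5. In lists as dense as those of day 5, merging itself evens out the counts of a chromosome. Chromosome 6 went from 88 lost and 206 gained regions to 49 and 54, and chromosome 19 from 155 and 22 to 18 and 12. The setting therefore cannot decide whether the day 5 calls hold.

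Lost regions were wider than gained ones in 3 comparisons. The median width was 917 bp against 860 bp in ZR751 on day 2 (permutation test, adjusted p = 0.0282), 964.5 bp against 772.5 bp on day 2 (adjusted p = 0.0282) and 902 bp against 797 bp on day 5 (adjusted p = 0.0030) in the unnamed set. In ZR751 on day 5 (918 bp against 904 bp), in MCF7 on day 5 (781 bp against 746 bp) and in MCF7 on day 2 (896 bp against 575 bp) the difference did not pass the threshold (adjusted permutation p = 0.383, 0.428 and 0.0907).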

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

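The test of regions with a score of at least 50 was chosen after its result was seen; the other tests of explanations below were chosen before they were run.

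The following were picked out because the same treatment gave different shares of lost regions in 2 sets or on 2 days, by a test of the difference. The tests between days took the days as independent, although many regions were listed on both. The odds ratio of lost over gained was 14.8 between day 2 and day 5 in MCF7 and 4.43 in the set that names no cell line. It was 0.201 between ZR751 and the unnamed set on day 2, 6.46 between ZR751 and MCF7 on day 5, and 0.136 between MCF7 and the unnamed set on day 5. No explanation was tested for these.

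The excess of lost over gained regions at gene ends in ZR751 also differed between days: the odds ratio was 0.928 on day 2 and 2.60 on day 5 (exact test of equal odds ratios, p = 0.00483, adjusted p = 0.0145 over 3 tests). The test took the 2 days as independent, but 1254 of the 1553 regions of day 2 were listed again on day 5. Its p-value therefore cannot be taken at face value. Gene-dense chromatin, which goes with GC content, is argued against as the whole cause, since within 5 classes of the gene density around each region the odds ratio was 2.45 (permutation p = 1e-04, the smallest possible). The low-scored regions of the longer list as the only source stay open: with a score of at least 50, 204 of 2661 lost and 45 of 1381 gained regions lay at gene ends, an odds ratio of 2.47 (Fisher exact test, p = 7.753e-09), which does not go with that explanation, but the test was chosen with its result known and takes scores as comparable between lists, which is not stated. List length itself stays open too, since among only as many top-scored regions as the day 2 lists hold, 41 lost and 20 gained regions lay at gene ends, an odds ratio of 1.57 (Fisher exact test, p = 0.114), which is too imprecise to decide. No biological explanation was tested; treatment time, the design's own variable, stays open, and GC content itself was not measured without sequence.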

How the results depend on the processing

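A stricter score was planned for the counts of regions; its bound of 50, its use for overlap and gene ends, gene span assignment and the smaller adjustment family were chosen after seeing the data, and one bound for all lists takes their scores as comparable, which is not stated. No paired analysis was possible because the lists hold no value per library, and how replicates entered them is not given in the sources used here. For the same reason no replicate could be left out and no other splits of libraries could be made. The 4 motif alternatives and the GC comparison were not run, since they need sequence. Limits of depth cannot be given, as the lists hold no counts. Of 1231 recomputed values, 840 were classed as unchanged, 362 moved, 23 reversed, 3 became stronger and 3 weaker. For tests, unchanged meant the same direction and side of the threshold. Of the 840, 607 were counts for single named genes (lost minus gained regions), where the class also held counts that changed in size. Within 10 kb of a gene end, C4BPA in ZR751 on day 2 went from -2 to -1 and was classed as unchanged. Merging of regions under 1 kb apart gave 242 of the 607. Unchanged were every agreement of direction under reciprocal overlap, centre distance and gene-end removal, the clustering at 1 Mb and after merging, and the estrogen receptor list of ZR751 on day 5 under each gene assignment.

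With a score of at least 50, the share lost rose to 71.1% (ZR751 day 2), 65.8% (ZR751 day 5), 96.7% (unnamed day 2) and 69.0% (unnamed day 5), because lost lists had higher scores; the ZR751 difference between days passed the threshold (odds ratio 1.28); agreement stayed at 100% but was no longer past the threshold for MCF7 day 2 and day 5 and for ZR751 and the unnamed set on day 2, with fewer regions; and the gene end odds ratio of MCF7 on day 5 became 0. With regions under 1 kb apart merged, the odds ratio between ZR751 days, 1.01 before, was 0.99958. The gene end odds ratio turned to 0.805 in the unnamed set on day 5 with a window of 2500 bp, and to 0.810 in MCF7 on day 5 with all annotated genes. The chromosome calls fell to 0 in ZR751 on both days with regions under 1 Mb apart merged, a setting that by itself evens out the dense lists of day 5. The neighbour share of MCF7 on day 5 was 85.7% under 10 kb, over only 7 pairs and against a permuted mean of 71.6%. Without gene ends, the width difference of ZR751 on day 5 was -4.5 bp.

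For estrogen receptor targets in ZR751 on day 2, the log2 odds ratio (0.5 added to each count) was 4.08 with regions as the unit and 3.09 with the smaller adjustment family, both now past the threshold, while it was 3.63 within 10 kb (adjusted exact p = 0.639), 2.85 with all annotated genes (adjusted exact p = 1) and 2.99 by gene span (adjusted exact p = 0.0947), not past it. Lists that were not past the threshold in any setting changed sign as follows, in the same unit. Within 10 kb of a gene end in ZR751 on day 5, immune markers were at 0.90, cell cycle at 1.64 and MYC and growth at -0.69. With all annotated genes, ZR751 day 5 had luminal identity at -0.022, basal at 0.35, immune at 1.20 and AP-1 at -1.97; MCF7 day 5 had mesenchymal, AP-1 and neuronal each at 0.68; and unnamed day 2 had basal at -0.91. With regions as the unit in ZR751 on day 5, luminal identity was at -0.021 and AP-1 at -0.39. Of the named genes, lost minus gained regions turned to -1 for MYCN in ZR751 on day 5 and PIK3R1 in unnamed day 2 within 10 kb, to 1 for RHOBTB1 and TP63 in ZR751 on day 5 and to -1 for PIK3R1 in unnamed day 2 with all annotated genes. Beyond these, 356 gene counts moved, 327 of them to 0: 168 of 184 within 10 kb, 154 of 167 with all annotated genes and 5 of 5 by gene span, settings that drop far regions or assign them to other genes. The cause of the other changes was not tested.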

Other observations

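The predictions behind the tests of explanations below were written before those tests were run; the loci of the first paragraph were chosen after their values were seen.

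A region that shared the highest score, 5000, with others among the lost regions of ZR751 on day 5, at 76767851 to 76774534 of chromosome 11 and 11.1 kb from TSKU, which codes for a secreted leucine-rich protein, overlapped the 4th ranked gained region of MCF7 on day 5 at 76767639 to 76771850. Of the 6 regions lost in ZR751 and gained in MCF7, others lay near CFAP58, ZG16B, SLIT3, SLC25A51 and SLC25A46. Between ZR751 and the unnamed set, MMP10 and RAB38 were nearest to regions lost in ZR751 (ranks 189 and 163) and gained in the unnamed set (ranks 70 and 61). The widest region of any list, 34945 bp at 1730131 to 1765075 of chromosome 11, was lost in ZR751 on day 5, is also 1 of the 8 with a score of 5000, and holds the whole of IFITM10 and of the estrogen target CTSD, to which 4 further lost regions were assigned. A region gained in ZR751 on day 2 (100713006 to 100716421 of chromosome 15, rank 4) lay between genes, 63.0 kb from ASB7, the nearest protein-coding gene. It overlapped one gained in MCF7 on day 5 (100712842 to 100717034, rank 2), while ASB7 had 0 regions in ZR751 on day 5.

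For the estrogen receptor targets in ZR751 on day 5, 3 technical explanations were weighed. An imbalance of lost and gained regions between chromosomes is argued against, since the odds ratio within chromosomes was 22.4 (permutation p = 1e-04, the smallest possible). Gene density, which goes with GC content, is argued against as the whole cause by an odds ratio of 22.3 within 5 classes of gene density (permutation p = 1e-04). Assignment of far regions to the wrong gene is argued against as well: within 10 kb of a gene end 16 list genes were lost and 0 gained, a log2 odds ratio of 4.38 with 0.5 added to each count (Fisher exact test, p = 0.000486). A lower estrogen receptor activity under inhibitor is one biological hypothesis, untested here without receptor binding, motifs or expression.

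For the shared direction of neighbouring regions in ZR751 on day 5, 1 element split into several regions is argued against, since of 1275 pairs 20 to 100 kb apart 77.2% had the same direction, 26.3 points above the permuted mean. An imbalance between chromosomes does not account for it, with an excess of 26.6 points when directions were permuted within chromosomes. A trend over megabases explains part of the raw excess at most: permuted within windows of 5 Mb, the mean was 61.3% and the excess 20.6 points. The excess was present for pairs under 10 kb apart (94.4% against 50.9%) and under 1 Mb (67.8% against 50.9%), so no domain size was measured, and no biological explanation was tested.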
